A study of Mus musculus with 6 samples.

How the data were processed

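RNA was measured in 6 libraries of mouse bone-marrow-derived macrophages (BMDMs), 3 from cells given Cas9 and guide RNAs against Maf and Mafb (double knock-out, dKO) and 3 from cells given Cas9 and scrambled guide RNA (control). Per the labels' protocols, bone marrow cells were electroporated with the Cas9 complexes at the start of differentiation, and cultured for 6 days in medium with serum and an M-CSF source. Smart-seq2, a full-length cDNA method that marks neither strands nor molecules, was applied to 5 ng of bulk RNA per library, with 15 cycles of cDNA amplification and 12 cycles of library amplification before sequencing of single 75-nucleotide reads. All 6 libraries carry batch number 1. Nothing in the labels says that the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

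The authors deposited 1 table with RPKM values (reads per kilobase of gene, scaled to library size) for each library, per the file headers. The submitters' processing notes name STAR 2.5.3, featureCounts, R 3.4.1 and the edgeR package 3.20.7, with the mouse build mm10, but no roles. The annotation is not given in the sources used here. The table also holds the authors' log2 fold changes, and the authors' p-values with false discovery rates. A further column, which its header calls −log10 of p, equals −log10 of the authors' false discovery rate in every deposited row. A second block repeats the values of 199 of the genes.

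The deposited table holds 422 genes chosen by the authors for their difference. Each has a false discovery rate of 0.0415 or lower and an absolute log2 fold change of 1.0008 or more in the authors' deposited table, and a highest RPKM of at least 1.53. Genes outside this selection were not analysed here. Tests on these genes therefore describe the size of each difference against the replicate spread, and their adjusted p-values are no independent evidence of change. Of the 422 symbols, 418 matched exactly 1 gene of the GENCODE vM21 annotation (GRCm38, the assembly behind mm10), which gave the coordinates and exon lengths used here. Of these, 403 genes are protein-coding and 15 of other types. Smart-seq2 reads carry no strand, and 22 genes overlap exons of another gene on the same strand and 91 on the other strand, so shared reads cannot be assigned for those parts.

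The library size behind each column was recovered from the deposited RPKM values. Multiplied by exon length and by 1 library size per library, they gave whole reads, within 0.05 of a read, for 99.5% to 99.8% of the 418 matched genes (chance gives 10%). The library sizes that did so were about 20084307, 18381131 and 23934059 for control replicates 1 to 3, and 15556552, 15147937 and 19991585 for dKO replicates 1 to 3. They are the sizes that scaled the RPKM values. Whether they equal the reads counted or include a normalization factor cannot be told from the values. Reads of one molecule can be counted repeatedly after amplification, so limits from counts cover counting error only. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 7.92 or more for each pair, so each library was counted once. No table of all measured genes was used here, so normalization across the transcriptome was left as the authors made it.

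Differences between dKO and control were tested with limma (version 3.58.1, R 4.3.3), with an intensity trend, on log2(RPKM + 1), without a filter or covariate. Benjamini-Hochberg adjustment was made over the 422 genes, at a threshold of 0.05. On this scale a log2 difference understates the change of genes with low values, so folds in the text are ratios of group mean RPKM. For a gene at 0 in all libraries of a group, the fold is a lower bound against 3 reads over the group. A single gene compared between 3 and 3 libraries cannot give an exact permutation p below 0.1.

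Before the data were examined, 25 gene lists holding 660 genes were fixed from general knowledge: resident and perivascular macrophage markers, complement and apoptotic cell clearance, MHC class II presentation, dendritic cell markers, macrophage self-renewal and proliferation regulators, alveolar macrophage markers, cell cycle, secreted factors acting on vessels, extracellular matrix and proteases, inflammatory cytokines and chemokines, interferon-stimulated genes, cholesterol and lipid handling, osteoclast genes, iron and haem handling, alternative activation, glycolysis and hypoxia, p53 response and macrophage core genes, with markers of monocytes, neutrophils and granulocyte precursors, mast cells with basophils and eosinophils, lymphocytes, erythroid and megakaryocyte cells, stromal and endothelial cells, and haematopoietic progenitors. Of these 660 genes, 113 were among the deposited genes. Because the table holds only selected genes, the planned form of the list test for that case was used. It compares genes called higher and lower inside a list with those outside it by a two-sided Fisher's exact test, for the 9 lists with at least 5 deposited genes, adjusted over those 9 lists. Such a test treats genes as units, so it describes these libraries only.

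The rule for named genes was also set before the data were examined. It takes the 10 largest differences on the log2(RPKM + 1) scale in each direction, past the test and without overlap between the groups. It leaves out clone-like names and pseudogenes, and then takes up to 4 called members per list by the smallest adjusted p. It gave 70 genes, with adjusted p from 3.58e-06 to 0.00213. Genes with low values rank lower on that scale. The rise with the largest ratio of mean RPKM, Sapcd2 (14.5-fold, chosen after its value was seen), is not among the 70. Beyond that rule, all called members of a list are named where 5 or fewer were called. Other genes were chosen after their values were seen: the interferon genes Ifit1, Ifit2, Ifit3, Ifit3b and Cmpk2, the cell cycle genes Mki67, Cdk1, Mcm2 and Mcm5, the monocyte genes Ly6c2 and Ccr2, the neutrophil genes S100a8, S100a9, Ngp, Prtn3 and Il1r2, Apoc1, Thbs2, and those given first among the additional observations.

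The alternatives were a pseudocount of 0.1, leaving out each library, the replicate number as a block, stricter limits on the authors' values, list tests without shared members or clone-like names, and a permutation test against random deposited genes of similar mean RPKM. Alternatives added after seeing the data were limma voom on the recovered reads, the same on reads thinned to 1 depth, omission of the genes with the lowest mean RPKM (316 of 422 kept), and the camera list test with a preset correlation of 0.01 and with an estimated one. On data simulated for the dKO against control comparison from 418 of these genes, with 200 changed, limma on log2(RPKM + 1) recovered 98% of 2-fold and 100% of 4-fold changes. It called 6 of the 218 unchanged genes. It estimated a 2-fold change as a median of 0.679 on the log2(RPKM + 1) scale. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.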

Results

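Expression was compared between macrophages grown from mouse bone marrow after Cas9 editing of both Maf and Mafb (dKO, 3 libraries) and macrophages from cells given a scrambled guide RNA (control, 3 libraries). Maf and Mafb encode related transcription factors of the macrophage lineage, and the series addresses the programme that cMAF directs in perivascular macrophages of the brain, for which these cultured cells serve as an editable model. Library sizes, estimated from the values, were about 18381131 to 23934059 in controls and 15147937 to 19991585 in dKO libraries, and may include a normalization factor. Recovered reads of the 418 deposited genes with a matched exon length came to 4.07% to 4.97% of that size in controls and 2.34% to 2.46% in dKO libraries. The edited genes themselves, Maf (chromosome 8, 115682942 to 115707794, minus strand, GRCm38/mm10) and Mafb (chromosome 2, 160363703 to 160367065, minus strand), were not analysed here, so their transcripts could not check the labels. Small insertions and deletions left by Cas9 need not lower a transcript. Per the labels, editing was examined at the target sites and by western blot.

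In dKO, all 12 deposited markers of resident macrophages, all 5 complement and clearance genes, all 5 iron genes, 5 of 6 cholesterol genes and 14 of 16 neutrophil markers were lower, while all 32 cell cycle genes were higher. Each of these lists passed Fisher's exact test (adjusted p from 9.31e-06 to 0.0204), but none passed by camera with an estimated correlation (adjusted p from 0.175 to 0.283). Several of these lists share members. Of the 422 genes, 283 were higher and 138 lower in dKO (limma, adjusted p up to 0.0414). Thbs2, an extracellular matrix gene, did not pass (4.22 ± 4.10 RPKM in controls, 1.52 ± 0.349 in dKO, mean ± SD, n = 3 per group as throughout; adjusted p = 0.108). Control replicate 3 carried its difference, which was 2.77-fold with all libraries and 1.23-fold without that replicate, and without control replicate 1 it was 3.70-fold and passed (adjusted p = 0.00533). The values of the groups did not overlap for 420 genes (99.5%, where chance gives 10% of unselected genes), and overlapped for Thbs2 and Wfdc21. Genes that were higher in dKO had a median of 1.26 RPKM in controls and a median rise of 2.95-fold. Genes that were lower had a median of 9.22 RPKM in controls and a median fall of 2.67-fold. The genes had been selected by the authors for this difference, so the calls are no independent evidence.

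**Figure D1:**
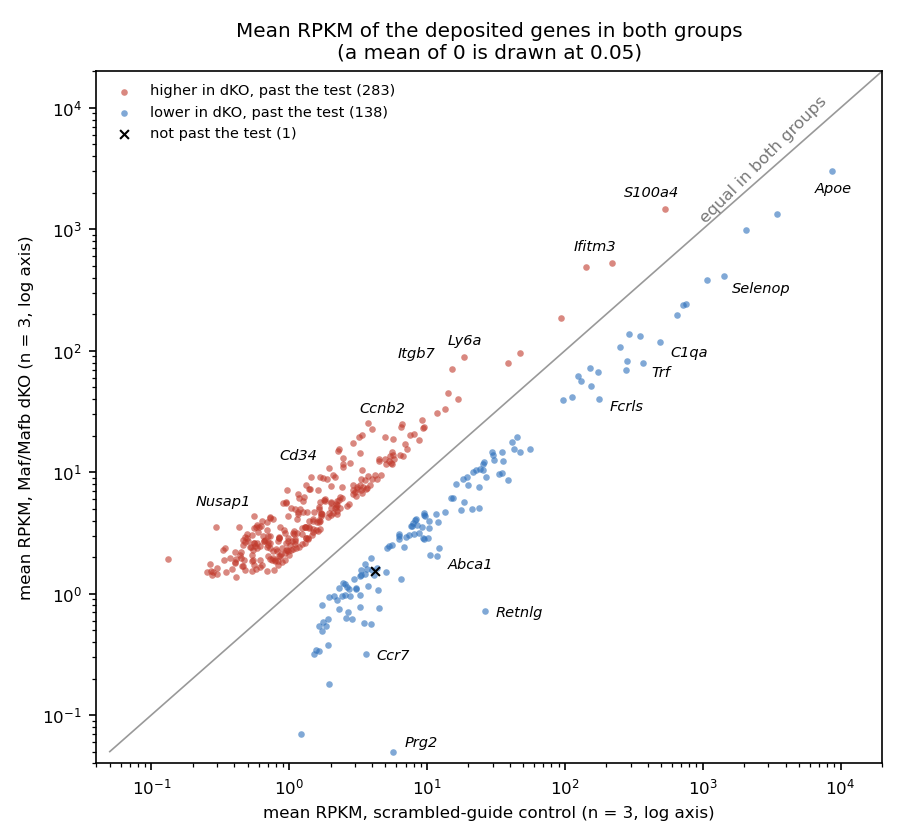
Mean RPKM of each deposited gene in control (horizontal, log axis) and dKO macrophages (vertical, log axis), n = 3 libraries per group, with 1 point per gene. The 283 genes higher in dKO lie mostly at low control RPKM (median 1.26), and the 138 lower genes reach up to Apoe at 8617 RPKM in controls.

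Markers of resident and perivascular macrophages fell together. Of 28 listed genes, 12 were among the deposited genes and all 12 were lower in dKO, by 2.10-fold to 3.51-fold with a median of 2.95-fold. Stab1, a scavenger receptor (chromosome 14, 31139013 to 31168641), fell from 155 ± 8.78 to 51.4 ± 1.52 RPKM. Selenop, which encodes the secreted selenium carrier selenoprotein P (chromosome 15, 3268547 to 3280508), fell from 1424 ± 189 to 411 ± 37.6 RPKM. Fcgrt, the neonatal Fc receptor, fell from 112 ± 1.26 to 41.8 ± 5.36 RPKM, and the mannose receptor gene Mrc1 from 35.8 ± 7.73 to 12.4 ± 2.64 RPKM. Lower calls were more frequent in this list than among other deposited genes (two-sided Fisher's exact test, adjusted p = 9.31e-06 over 9 lists). Camera, which compares the size of differences and not calls, did not pass with an estimated correlation (adjusted p = 0.175). It passed with the preset one (camera, adjusted p = 5.21e-06). That all 12 also passed when adjusted over the list alone adds nothing, since each had already passed over the 422 genes. In the same dKO libraries, 14 of 16 deposited neutrophil markers were lower and 2 higher, and 7 of 8 monocyte markers were higher and 1 lower.

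Of 33 listed complement and clearance genes, 5 were deposited and all 5 were lower, 3 of them subunits of C1q. The other 28 were not analysed, so the list as a whole cannot be judged. The subunits of complement C1q, which opens the classical pathway, lie side by side on chromosome 4. C1qa (136895917 to 136898803) fell 4.17-fold, from 491 ± 66.8 to 118 ± 4.85 RPKM. C1qb fell 2.57-fold, from 3465 ± 468 to 1347 ± 79.2 RPKM, and C1qc fell 2.82-fold, from 1073 ± 153 to 380 ± 15.4 RPKM. The receptor gene C5ar1 fell 2.66-fold, and Stab1, shared with the preceding list, 3.03-fold. The list's test gave an adjusted p of 0.0054 (two-sided Fisher's exact test), and camera an adjusted p of 0.175 with an estimated correlation. The iron and cytokine lists, also with 5 deposited genes and all 5 lower, gave the same value in Fisher's exact test. Against random deposited genes of similar RPKM the adjusted p was 0.081 (permutation test).

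All 4 deposited genes of MHC class II presentation (of 15 listed) were lower in dKO. H2-Eb1 fell 4.52-fold, from 38.6 ± 9.35 to 8.54 ± 1.25 RPKM, H2-Ab1 3.54-fold and H2-Aa 3.15-fold. These encode chains of the molecules that present peptides to T cells. H2-DMb2, which helps to load them, fell 2.5-fold, from 2.41 ± 0.462 to 0.963 ± 0.141 RPKM. In the same libraries Ccr7, the only deposited dendritic cell marker, fell 11.3-fold. Of other markers, 14 of 16 for neutrophils were lower and 2 higher, and 7 of 8 for monocytes were higher and 1 lower. A list of 4 lay under the size set for the list test. As a family formed after the values were seen, these 4 genes did not pass adjustment (two-sided Fisher's exact test, p = 0.0112, adjusted p = 0.112 over 10 families). That decides nothing, since all 4 were lower and a family of 4 could give no smaller p.

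Iron and haem genes were lower in dKO in all 5 cases (of 24 listed). Trf, the transferrin gene (chromosome 9, 103204001 to 103230444), fell 4.67-fold, from 372 ± 26.5 to 79.5 ± 6.98 RPKM, and it overlaps exons of Gm20425 on its strand. Slc40a1, the iron exporter ferroportin, fell 3.28-fold, and Cd163, the haemoglobin scavenger receptor, 3.13-fold. Spic, a transcription factor of iron-recycling macrophages, fell 3.44-fold. Lcn2, whose product binds bacterial iron carriers and is also a neutrophil granule protein, fell 3.23-fold. Slc40a1 and Cd163 are also counted among the resident macrophage markers and Lcn2 among the neutrophil markers. So 3 of the 5 iron genes are shared with other lists. The list's adjusted p was 0.0054 (two-sided Fisher's exact test), and 0.194 by camera with an estimated correlation.

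Of 6 deposited genes of cholesterol and lipid handling (of 42 listed), 5 were lower in dKO. Abca1, the exporter of cholesterol to apolipoproteins (chromosome 4, 53030787 to 53159895), fell 5.87-fold, from 11.9 ± 1.81 to 2.03 ± 0.256 RPKM. Apoe, the most abundant deposited transcript, fell 2.83-fold, from 8617 ± 1149 to 3047 ± 390 RPKM. The phospholipid transfer gene Pltp fell 2.63-fold, Apoc1 2.5-fold and Angptl4, an inhibitor of lipoprotein lipase, 2.24-fold. Lss, which encodes lanosterol synthase of cholesterol synthesis, rose 2.01-fold, from 2.72 ± 0.206 to 5.45 ± 0.355 RPKM. The list's adjusted p was 0.0204 (two-sided Fisher's exact test), 0.194 by camera with an estimated correlation, and 0.0625 without Angptl4, which another list shares.

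**Figure D2:**
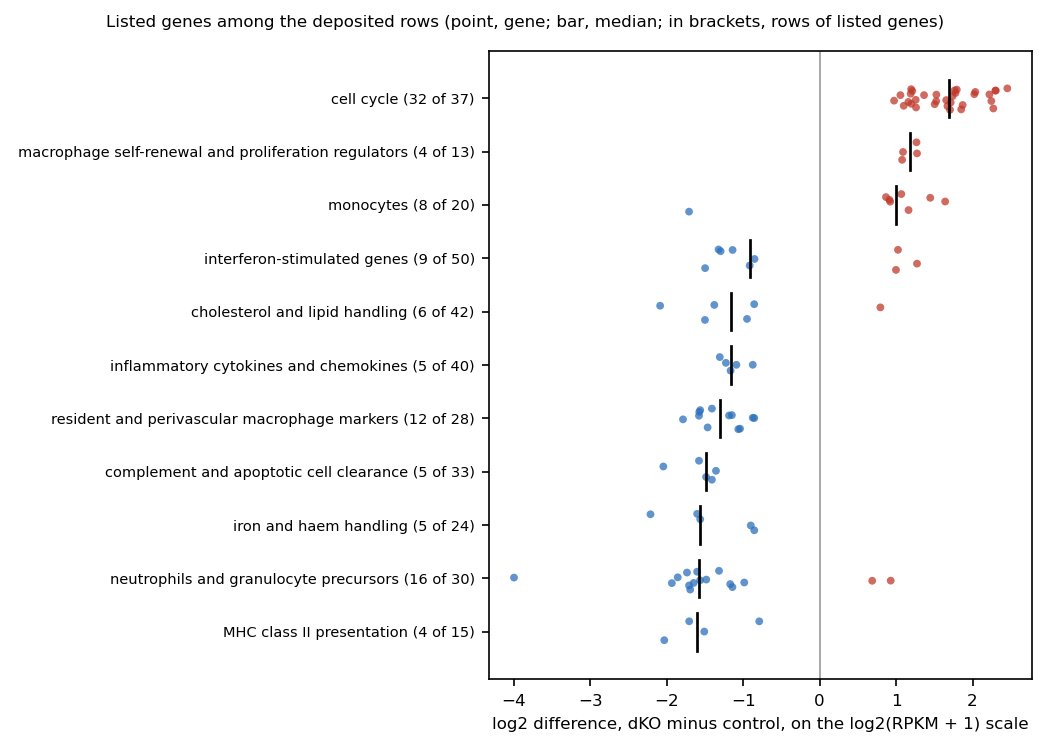
Difference between dKO and control for each deposited member of the lists with at least 4 deposited genes, on the log2(RPKM + 1) scale (horizontal), with 1 point per gene and a bar at the list's median. All 32 cell cycle genes lie above 0, and all 12 resident macrophage markers lie below it.

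Cell cycle genes rose in dKO. Of 37 listed genes, 32 were deposited and all 32 were higher, by 2.07-fold to 7.77-fold with a median of 4.80-fold. Cyclin B2, encoded by Ccnb2 (chromosome 9, 70407692 to 70421547), drives entry into mitosis, and its transcript rose from 3.75 ± 0.782 to 25.2 ± 6.20 RPKM. Ccna2, encoding cyclin A2, rose from 2.31 ± 0.315 to 15.4 ± 2.03 RPKM, and the mitotic kinase gene Plk1 from 3.21 ± 0.640 to 19.4 ± 3.36 RPKM. Nusap1, a spindle gene, rose 7.77-fold, Bub1b of the spindle checkpoint 7.30-fold, Birc5 6.66-fold and Kif20a 5.22-fold. Cdca3 rose 6.01-fold, Ube2c 5.97-fold and Cdc20 5.61-fold, and all are known to act in protein degradation at mitosis. Top2a rose 5.09-fold and the proliferation marker Mki67 5.84-fold. Cdk1 rose 2.56-fold. The replicative helicase gene Mcm2 rose 2.36-fold and Mcm5 3.63-fold. Higher calls were more frequent in the list than among other deposited genes (two-sided Fisher's exact test, adjusted p = 9.31e-06). The list did not pass by camera with an estimated correlation (adjusted p = 0.283), and did with the preset one (adjusted p = 3.3e-05). That all 32 also passed when adjusted over the list alone, as did the called members of every other list, adds nothing. Each had already passed over the 422 genes. In the same libraries, 7 of 8 deposited monocyte markers and 2 of 2 progenitor markers were higher and 1 monocyte marker was lower, and 14 of 16 neutrophil markers were lower and 2 higher.

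The 4 deposited regulators of self-renewal and proliferation (of 13 listed) were all higher in dKO. Foxm1, a transcription factor of mitotic genes, rose 5.65-fold, from 0.337 ± 0.0473 to 1.91 ± 0.697 RPKM. E2f2 rose 3.46-fold, the histone methyltransferase gene Ezh2 3.45-fold and cyclin E1, encoded by Ccne1, 3.21-fold. Of the 26 genes listed for the p53 response, Gtse1 (4.52-fold) and Ckap2 (6.13-fold) were deposited and higher, and both are known as genes of dividing cells.

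Among markers of other blood cells, those of monocytes were mostly higher in dKO, with 7 of 8 deposited genes (of 20 listed). S100a4, the most abundant of them, rose 2.73-fold, from 536 ± 71.1 to 1461 ± 190 RPKM, and it overlaps exons of Gm42674 on its strand. Ly6c2, which marks classical monocytes, rose 3.15-fold, from 14.2 ± 5.14 to 44.6 ± 6.39 RPKM. The chemokine receptor gene Ccr2 rose 2.07-fold, Treml4 2.84-fold and the coagulation gene F10 2.31-fold. Cd177, also a neutrophil marker, fell 4.86-fold. The list did not pass against the other deposited genes (two-sided Fisher's exact test, adjusted p = 0.282). That decides nothing about a rise, since most deposited genes were higher. Even 8 of 8 genes higher would not pass (two-sided Fisher's exact test, p = 0.0574 before adjustment). Lower genes were the minority, so lists with all 5 genes lower could pass the same test. Both deposited progenitor markers (of 20 listed) rose. Ly6a, encoding Sca-1 (chromosome 15, 74994877 to 74998031), rose 4.74-fold, from 18.6 ± 1.65 to 88.0 ± 11.8 RPKM, and Cd34 5.47-fold, from 1.96 ± 0.172 to 10.7 ± 0.433 RPKM. Itgb7, an integrin gene outside the lists, rose 4.71-fold, from 15.1 ± 2.21 to 71.0 ± 1.37 RPKM.

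Neutrophil and granulocyte precursor markers changed in the same libraries, with 14 of 16 deposited genes (of 30 listed) lower and 2 higher. Retnlg, a resistin-like gene of neutrophils (chromosome 16, 48872621 to 48874496), had the largest fall of any named gene with reads in both groups, 36.8-fold, from 26.5 ± 9.29 to 0.720 ± 0.550 RPKM. Camp, encoding the granule peptide cathelicidin, fell 4.25-fold, lactoferrin (Ltf) 3.44-fold and Chil1 3.43-fold. S100a8 fell 3.33-fold, with 848, 752 and 362 RPKM in control replicates 1 to 3 and 187, 226 and 177 RPKM in dKO replicates 1 to 3. S100a9 fell 3.11-fold. Prtn3, encoding proteinase 3 of early granulocyte precursors, rose 2.24-fold, from 1.91 ± 1.10 to 4.27 ± 0.636 RPKM, and the decoy receptor gene Il1r2 rose 2.39-fold. Lower calls were more frequent in the list than elsewhere (two-sided Fisher's exact test, adjusted p = 1.92e-05). The list did not pass by camera with an estimated correlation (adjusted p = 0.194), and did with the preset one (adjusted p = 9.93e-06). The list shares Lcn2, Mmp9 and Cd177 with the iron, matrix, osteoclast and monocyte lists.

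Other cell types had few deposited markers. Prg2, which encodes eosinophil major basic protein, was the only one of 21 listed markers of mast cells, basophils and eosinophils. It was listed at 3.33, 12.5 and 1.10 RPKM in control replicates 1 to 3 and at 0 in all dKO libraries. With 270 control reads, it was at least 73.1-fold lower against a floor of 3 reads over the dKO group. Control replicate 2 held 192 of these reads, and without it the bound was 29.9-fold. Without dKO replicate 3, which leaves fewer reads behind the 0, the bound was 44.3-fold. Of 29 lymphocyte markers only Cd4, which some macrophages also express, was deposited, and it fell 5.13-fold, from 12.3 ± 1.15 to 2.39 ± 0.943 RPKM. Of 24 erythroid and megakaryocyte markers, the platelet chemokine genes Pf4 (3.01-fold) and Ppbp (4.58-fold) fell. Vwf, which is also the only deposited one of 27 stromal and endothelial markers, rose 2.68-fold, from 2.91 ± 0.451 to 7.80 ± 0.560 RPKM. The chemokine receptor gene Ccr7, the only one of 27 dendritic cell markers, fell 11.3-fold, from 3.64 ± 0.746 to 0.321 ± 0.252 RPKM. Of 30 macrophage core genes only Lyz1 was deposited, and it fell 2.05-fold, from 9.45 ± 0.232 to 4.60 ± 0.135 RPKM.

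**Figure D3:**
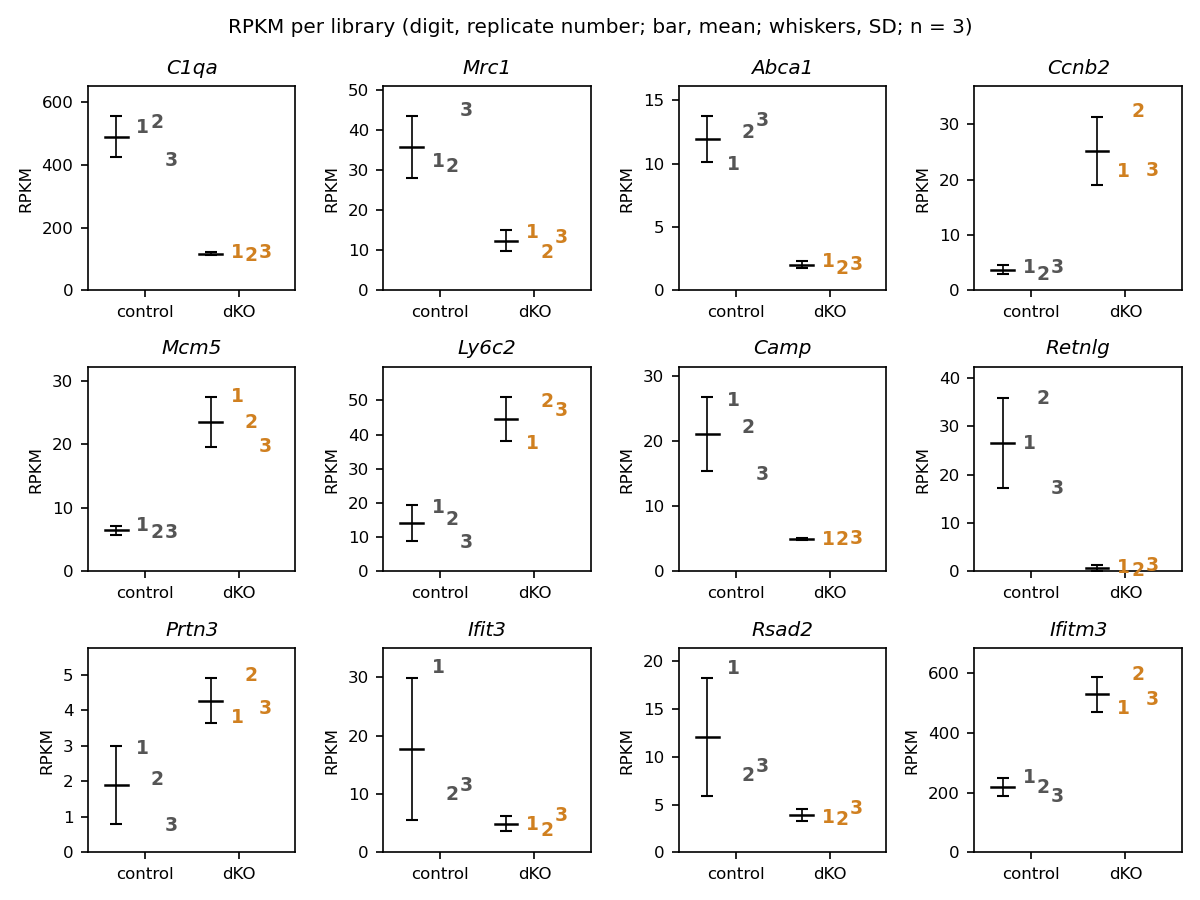
RPKM of 12 genes in each library (vertical, linear axis from 0), with the digit giving the replicate number, the bar the group mean and the whiskers the SD (n = 3). Ifit3 and Rsad2 stand highest in control replicate 1 (31.7 and 19.2 RPKM), and Camp stands lowest among controls in replicate 3 (14.9 RPKM).

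Inflammatory cytokines and chemokines were lower in all 5 deposited cases (of 40 listed). Il1rn, the interleukin-1 receptor antagonist, fell 2.43-fold, from 30.9 ± 1.44 to 12.7 ± 1.59 RPKM, Ccl5 2.94-fold, Ccl12 2.60-fold and Ccl24 3.51-fold. Cxcl10, an interferon-inducible chemokine gene, fell 3.54-fold with all libraries and 1.53-fold without control replicate 1, which held 21.7 RPKM against 5.17 and 3.64 RPKM in the other controls. Its adjusted p was 0.0414 (limma), and it passed 0.05 no longer without dKO replicate 1 (0.0673), 2 (0.0776) or 3 (0.0906). The list's adjusted p was 0.0054 (two-sided Fisher's exact test), and 0.217 by camera with an estimated correlation.

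Interferon-stimulated genes moved both ways, with 6 of 9 deposited genes (of 50 listed) lower and 3 higher. The list did not pass (two-sided Fisher's exact test, adjusted p = 0.0724), which with 9 genes does not exclude a difference. Rsad2, encoding the antiviral enzyme viperin, fell 3.09-fold, from 12.1 ± 6.19 to 3.91 ± 0.630 RPKM. Ifit1 fell 3.24-fold, Ifit2 2.31-fold, Ifit3 3.60-fold, Ifit3b 4.24-fold and Cmpk2 2.55-fold. Control replicate 1 carried much of this difference. Without it, the falls were 2.03-fold for Ifit1, 1.53-fold for Ifit2, 2.17-fold for Ifit3, 2.43-fold for Ifit3b, 1.62-fold for Cmpk2 and 2.17-fold for Rsad2, and all 6 stayed past the test. Ifit2 did not pass without dKO replicate 2 (limma, adjusted p = 0.0643). Ifitm3, which restricts virus entry, rose 2.42-fold, from 218 ± 31.3 to 528 ± 59.2 RPKM. Oas3 rose 2.17-fold and Ly6e 2.00-fold.

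Few genes of the remaining lists were deposited. Of 51 secreted factors acting on vessels, 2 were deposited and both fell: the growth factor gene Pdgfc 3.77-fold, from 2.65 ± 0.298 to 0.703 ± 0.108 RPKM, and Angptl4 from 6.27 ± 0.282 to 2.80 ± 0.598 RPKM. Of 43 matrix and protease genes, Mmp9 fell 5.01-fold, from 10.5 ± 1.16 to 2.09 ± 0.898 RPKM, and Mmp27 2.58-fold. Mmp9 and the proton pump subunit gene Atp6v0d2, which fell 3.57-fold from 55.9 ± 6.30 to 15.6 ± 3.06 RPKM, were the 2 deposited osteoclast genes of 20 listed. Atp6v0d2 was also the only one of 21 alveolar macrophage markers. Of 24 alternative activation genes, Mrc1 (2.90-fold) and Ccl24 fell. None of 34 glycolysis and hypoxia genes was among those analysed here. Outside the lists, Fcrls, an Fc receptor-like gene, fell 4.43-fold, from 178 ± 5.39 to 40.1 ± 3.28 RPKM. Ms4a4a fell 3.97-fold, from 277 ± 16.7 to 69.9 ± 10.8 RPKM, and Il18bp, which encodes a secreted binder of interleukin 18, fell 4.73-fold, from 23.8 ± 3.73 to 5.04 ± 0.342 RPKM.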

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

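The calls were stable to the settings tried, within a table that the authors had selected for the difference. Voom, thinning, omission of the genes lowest in mean RPKM and both camera tests were chosen after seeing the data. Against 283 higher and 138 lower genes, a pseudocount of 0.1 and the replicate block gave the same genes, and leaving out a library gave 282 to 283 higher and 136 to 139 lower. Besides Cxcl10, Ifit2 and Thbs2, described above, the calls that ended were Gm13431 and Rtl8c without control replicate 2 (adjusted p = 0.0539 and 0.0504), and Hist1h4d without control replicate 3 (0.0666) or dKO replicate 2 (0.0548). Voom on recovered reads, with or without thinning, gave 279 and 138 of 418 genes, and that omission 198 and 117 of 316 genes. An absolute log2 fold change of at least 2 in the authors' deposited table left 96 higher and 26 lower genes, by its construction. All 763 values under an alternative of the 70 genes that the rule gave kept direction and call. The rule takes large differences and small adjusted p-values, so that count is no evidence of stability. Cxcl10 and Ifit2, named outside the rule, lost calls as described above. Of 163 list values under an alternative, 154 kept their side of the threshold and 9 did not. Of these, 7 came from camera with an estimated correlation: adjusted p = 0.175 for resident macrophage markers and for complement, 0.283 for cell cycle, 0.217 for cytokines, and 0.194 for cholesterol, iron and neutrophil lists. Lists left with fewer than 5 called genes were not tested: the cytokine list without any 1 dKO replicate, the cytokine, iron and complement lists without shared members, the cytokine and iron lists without the genes lowest in RPKM, the cytokine and cholesterol lists at the strictest false discovery rate, and all but the cell cycle and neutrophil lists at a log2 fold change of at least 2. Without the estimated correlation, the largest adjusted p over the alternatives that gave a test was 0.0048 (resident), 0.00369 (cell cycle), 0.0081 (cytokines), 0.0149 (iron) and 0.00045 (neutrophil). The other 2 were complement against matched random genes (adjusted p = 0.081) and cholesterol without shared members (0.0625). The cause was not tested. Replicate numbers gave no sign of pairing: deviations of equal numbers correlated at −0.14, 0.07 and −0.12. Pairing is not excluded, since only genes selected for the group difference were used and unequal numbers were not compared. The planned count-model tests and size factors were planned for deposited counts and were not run on the recovered reads, where voom was used instead; the planned run without a filter equals the reported one, and a mean expression column was not used here. Depth limits the genes near the floor, 4 of which are listed at 0 in at least 1 library.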

Other observations

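Of the 422 genes, 309 were in none of the lists, with 229 higher and 79 lower in dKO and Thbs2 not past the test, and the genes of this paragraph and the next were chosen after their values were seen. Among the lower ones, the receptor gene Gpr34 fell 2.07-fold, from 18.2 ± 1.75 to 8.77 ± 0.736 RPKM, and the transporter gene Slco2b1 fell 6.90-fold, from 3.91 ± 0.491 to 0.566 ± 0.323 RPKM. Aif1, encoding IBA1, fell 2.47-fold, from 97.5 ± 23.1 to 39.6 ± 0.527 RPKM, and Olfml3 2.26-fold. S1pr1, a receptor for sphingosine 1-phosphate, fell 2.17-fold, and Gpr65, a receptor that senses acid, 2.91-fold. The secreted peroxidase gene Gpx3 fell 2.12-fold, from 293 ± 27.9 to 138 ± 14.9 RPKM.

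Among the higher genes outside the lists, Ifi27l2a, known as interferon-inducible, rose 3.43-fold, from 143 ± 27.9 to 488 ± 113 RPKM. Uhrf1, which maintains DNA methylation through replication, rose 5.32-fold, from 2.48 ± 0.181 to 13.2 ± 0.885 RPKM. The calcium pump gene Atp2a3 rose 3.96-fold and the hexose transporter gene Slc2a6 2.92-fold. Acod1, which makes itaconate, rose 2.48-fold, from 9.41 ± 4.48 to 23.3 ± 2.39 RPKM. By symbol, 8 of 8 deposited Cenp genes of the kinetochore were higher, 8 of 8 Kif motor genes, 5 of 5 Mcm and 5 of 5 Hist1 histone genes (Hist1h4d not past the test without control replicate 3, adjusted p = 0.0666, or dKO replicate 2, 0.0548), while 3 of 3 C1q genes were lower. None of 10 such families passed by itself (two-sided Fisher's exact tests, lowest adjusted p = 0.112, for the 4 MHC class II genes). These tests decide nothing, since every family already lay wholly on 1 side. Even 8 of 8 genes higher gave only p = 0.0574 before adjustment (two-sided Fisher's exact test).

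Of the tests that follow, those of the neutrophil population, of interferon genes moving both ways, of Ifit paralogs, of control replicate 1, of progenitors, and the first comparison of mitotic with replication genes were chosen only after the result was seen. Whether the 14 lower neutrophil markers fell through a lower share of 1 uniform neutrophil population is left open: Cochran's Q over its degrees of freedom, a test of 1 common fold, was 2.92, but 1.76 without Retnlg, 2.96 without the shared Mmp9, Lcn2 and Cd177, and 1.36 without these 4, so the misfit rests mainly on Retnlg. Retnlg stood at 7.84%, 11.7% and 8.43% of Ngp RPKM in control replicates 1 to 3, and at 0.975%, 0.122% and 1.72% in dKO replicates 1 to 3. The granule and calprotectin genes Camp, Ltf, Ngp, Lcn2, Chil1, S100a8 and S100a9 gave a ratio of Q to its degrees of freedom of 0.32 around a common fall of 3.36-fold. These 7 were picked from the 14 after their folds were seen, so that value decides nothing, and whether a smaller share of such cells or a change within them lies behind their fall is left open. No single library made the pattern in this selected table, since all 14 stayed past the test whichever library was left out. Such retention is not particular to them: at least 136 of the 138 lower genes stayed in each omission.

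For interferon-stimulated genes, the 3 that rose, Ifitm3, Ly6e and Oas3, contradict a fall common to all deposited members. This restates the pattern already seen. It cannot exclude a weaker response, since 41 of the 50 listed genes were not among those analysed. The 6 lower genes varied together within groups (mean pairwise correlation 0.958, median of random sets of lower genes 0.087), mostly because of control replicate 1. Without it the correlation was 0.528, at percentile 96.2 of random sets. Reads shared between Ifit paralogs leave the fall of 2 genes outside that family, Rsad2 and Cmpk2, unexplained, and all 6 lower genes stayed past the test without control replicate 1. Covariation within groups does not bear on a difference between dKO and control. Staying past the test is not particular to these 6, since all 138 lower genes did so without control replicate 1. Outside the lists, the interferon-inducible gene Ifi27l2a rose 3.43-fold. A weaker response of these 6 genes in dKO remains only one hypothesis, and the size of their fall depends on control replicate 1.

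The median log2 fold of the 32 cell cycle genes was 2.26 before and 1.84 after a linear correction for gene length and GC content. The fit took in only 418 genes selected for a difference and had an R squared of 0.063. It could therefore remove little, and cannot exclude a bias from length or GC content. All 32 genes stayed past the test in each omission of a library, so no single library carried their rise in this selected table. Such retention is not particular to them: at least 282 of the 283 higher genes stayed in each omission. A higher share of undifferentiated progenitors could contribute and is left open: only 2 of 20 listed progenitor markers, Cd34 and Ly6a, were among the genes analysed, both higher. Split after their folds were seen, the 23 mitotic genes had a mean log2 fold of 2.42 and the 7 replication genes (Mcm2, Mcm4, Mcm5, Mcm7, Rrm2, Tyms and Tk1) of 1.5, a difference of 0.92, or 0.81 after correction for control RPKM, with Hmgb2 and Stmn1 put in neither. Both differences decide nothing, since a permutation of genes takes as independent genes that vary together (estimated correlation 0.388).

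Loss of chromosome ends beyond the Cas9 cuts was also tested. Of the deposited genes between Maf or Mafb and the distal chromosome end, 5 were lower and 5 higher, against 133 lower and 274 higher elsewhere (one-sided Fisher's exact test, p = 0.206), too few to decide. Of the 10 ways to split the 6 libraries into 3 and 3, only 1, the real one, gave as many genes past the test (421, highest other 0). With 10 splits the share cannot fall below 0.05, and the genes had been selected for the real split.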
